A study of Mus musculus with 12 samples.

How the data were processed

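RNA was measured in 12 libraries from mouse E14 embryonic stem cells that carried a tbGFP reporter of the 2-cell-like state. Cells were collected after culture with sorbitol for 0, 6 or 24 h and sorted into tbGFP-positive and tbGFP-negative cells, which gave 6 groups of 2 libraries. Groups were taken from GEO's labels, and every column mapped to a library (0 columns were not mapped). The labels number the libraries of a group as replicates 1 and 2 but do not say what the numbers mark or whether the libraries came from separate cultures. The sort used a reporter of the 2-cell program, so the comparisons of sorted fractions start from a difference in that program.

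Total RNA libraries were made with a stranded kit, per the labels' protocols. Reads were checked with FastQC, aligned with HISAT2 to mm10 and counted with featureCounts, and differential expression was tested with DESeq2, per the submitters' processing notes, which give no versions. The deposited files hold raw counts, 1 per Ensembl transcript, for 142446 transcripts, per the file headers. The strand setting and the handling of reads that overlap several transcripts are not stated. Counts of single genes did not settle whether reads shared by transcripts were left out. Actb, with 9 transcripts, had 0 to 14 counts per library and Eef2, with 3, had 14693 to 51055, but Hprt, with 1, had 1 to 23, Gapdh, with 13, had 143 to 861, and Tbp, with 12, had 40 to 396. Genes with 5 or more annotated transcripts had a median mean count of 15.75 and genes with 1 had 2.5. Levels are therefore compared between libraries, not between genes, and overlapping genes, antisense genes and near-identical copies are uncertain.

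The design assumed gene counts. Since the files hold transcript counts, these were summed per gene with GENCODE release M21 (GRCm38, the build of mm10), matched by transcript identifier without version: 141536 transcripts matched and 910 did not, and the latter, with 0.0606% to 0.0903% of the counts, were left out. The sums gave 55266 genes, of which 38071 had counts, and 19384 with at least 10 counts in at least 2 libraries were tested. Total counts for replicates 1 and 2 were 2306870 and 7344399 for tbGFP-negative and 6098314 and 4572157 for tbGFP-positive cells at 0 h, 6583584 and 5045092 and then 3581875 and 7832956 at 6 h, and 7900178 and 6415064 and then 6457729 and 7134401 at 24 h. A value of 3 counts corresponds to 0.31 to 1.12 CPM.

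The fit used edgeR 4.0.16 with TMM factors, the quasi-likelihood F test with robust estimation and a mean for each of the 6 groups, so that all 12 libraries shared the estimate of spread (common dispersion 0.208, or a coefficient of variation of 45.6%). The 7 comparisons between groups were tbGFP-positive against tbGFP-negative cells at 0, 6 and 24 h, and 6 h and 24 h against 0 h within each sorted fraction. The 2 interactions compared the gap between fractions at 6 h or 24 h with that at 0 h. P-values were adjusted with the Benjamini-Hochberg method within each comparison, at a threshold of 0.05. The SE of a log2 fold change was its absolute value divided by the square root of F. Counts were simulated for tbGFP-positive against tbGFP-negative cells at 24 h (19384 genes, 200 of them changed). In them 19% of 2-fold and 60% of 4-fold changes were called, and 4.82% of calls, 4 genes, were false. The simulated spread followed a trend with abundance only, and the groups had the same means apart from the changed genes. Changed genes were taken only above a least mean count. These rates may therefore not hold for the real libraries, whose genes and groups differ more.

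Where a group had no counts, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval. These bounds and intervals cover counting error only, and no molecular identifiers marked reads copied by PCR.

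Before the data were examined, 24 gene lists with 574 symbols in all, the comparisons, the naming rule and most alternatives were fixed. The lists covered the 2-cell program, naive pluripotency, formative and primed pluripotency, osmotic response, p53 targets, NRF2 antioxidant targets, ATF4 targets, immediate-early genes, heat shock, S phase, G2/M, ATR and DNA repair, repressors of the 2-cell program and chromatin factors, cholesterol synthesis, glycolysis and hypoxia, ribosome biogenesis, ribosomal proteins, replication histones and mitochondrial mRNAs, and markers of primitive endoderm, trophectoderm, mesoderm and ectoderm, fibroblasts and germline. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts of members adjusted over the list alone are given beside those adjusted over all genes.

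Genes were named by a rule. Per comparison between groups it took the 5 largest increases and the 5 largest decreases among called genes with a mean of at least 2 CPM in the higher group and no overlap between the libraries of the 2 groups, ranked by fitted log2 fold change. It left out predicted or clone-named models with symbols of Gm, LOC, AC, AL, BC or AU with digits, ending in Rik or holding -ps. Other clone-based symbols, such as CT009755.2 and CAAA01098150.1, were not covered by it and stayed in. It added a fixed panel of 20 genes, all of which were tested, and up to 2 members with the smallest adjusted p from each list that passed. The other genes in the text, such as further members of a list, were chosen after their values were seen.

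The alternatives fixed in advance were DESeq2 size factors or upper-quartile factors in edgeR, DESeq2 1.42.0 in place of edgeR, no filter on low counts, a stricter filter of 1 CPM in 4 libraries, only the groups of a comparison in the fit, the replicate number as a block, a fold above 2 as well, an estimated correlation for lists, and each library left out in turn. Alternatives chosen after seeing the data were library totals as the only scaling, tests per transcript, sums over protein-coding transcripts, genes with 1 annotated transcript, and fits without the tbGFP-positive group at 6 h. All of them ran. Work was done in R 4.3.3 and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.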

Results

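The series asked how hyperosmotic stress changes mouse embryonic stem cells and the rare 2-cell-like cells among them, which transiently express genes of the 2-cell embryo. E14 cells, a mouse embryonic stem cell line, carried a turboGFP (tbGFP) reporter of the 2-cell-like state. They were collected at 0, 6 or 24 h of sorbitol, a sugar alcohol that raises osmolarity, and were sorted into tbGFP-positive and tbGFP-negative cells. No group was kept for 6 or 24 h without sorbitol. Changes from 0 h may therefore come from sorbitol or from time in culture, which cannot be told apart here. The sort came after the culture, so a fraction at 6 or 24 h need not stem from the same fraction at 0 h. RNA was sequenced from 2 libraries in each of the 6 groups, 12 in all. The libraries held 2306870 to 7900178 counts. Group values are mean CPM, counts scaled to library size, ± SD with n = 2 libraries, and log2 fold changes are given ± their standard error (SE). Unless another test is named, adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 19384 genes. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

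The 2 sorted fractions stood apart on the main axis of variation, which held 69.4% of the variance. The tbGFP-positive libraries lay between 72.33 and 82.1 on it at all times. The tbGFP-negative libraries lay at -101.88 and -96.74 at 0 h, at -85.02 and -86.88 at 6 h, and at -49.27 and -49.68 at 24 h. The Zscan4 genes Zscan4a to Zscan4f, markers of 2-cell embryos and 2-cell-like cells, took 4.18% and 4.89% of all counts in tbGFP-positive cells at 0 h, 3.58% and 2.7% at 6 h, and 2.5% and 2.93% at 24 h. In tbGFP-negative cells they took 0.002% and 0.004% at 0 h, 0.005% and 0.004% at 6 h, and 0.088% and 0.085% at 24 h. The tbGFP-positive libraries at 6 h held fewer genes than the rest. Thinned to one depth of 2305061 counts, they showed 17049 and 16520 genes, against 17651 to 22870 in the other 10 libraries. The library with 17651 was replicate 2 of the tbGFP-positive cells at 0 h, so it was nearly as sparse, while replicate 1 showed 21539. Counts of the 2 tbGFP-positive libraries at 6 h also correlated less with each other across genes (Pearson r = 0.775) than those of the other groups (r = 0.924 to 0.972).

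**Figure D1:**
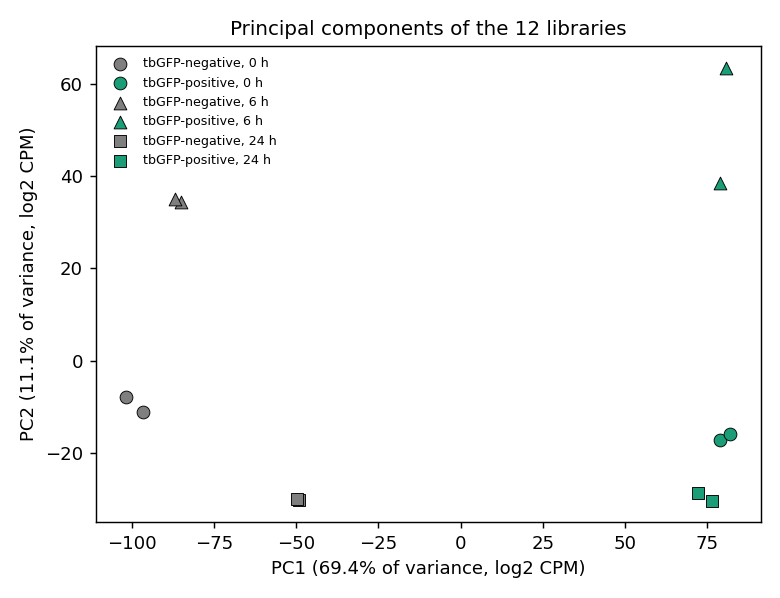
Principal components of log2 CPM in the 12 libraries, with 1 point per library, coloured by sorted fraction and shaped by hours of sorbitol; axes give the percent of variance. The tbGFP-negative libraries at 24 h (-49.27 and -49.68) lie nearer to the tbGFP-positive libraries on the first component than those at 0 h (-101.88 and -96.74).

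Before sorbitol, the comparison of the sorted fractions shows what set tbGFP-positive cells apart. Zscan4d was at 19000 ± 1170 CPM in tbGFP-positive cells and at 6.97 ± 2.99 CPM in tbGFP-negative cells, a log2 fold change of 11.29 ± 0.27 (adjusted p = 5.25e-13). Zscan4c (gene ENSMUSG00000054272.6, chromosome 7, 11005745 to 11010547, GRCm38) was at 11700 ± 846 against 8.24 ± 5.85 CPM. Duxf3 is the annotated name of Dux, a double-homeobox transcription factor that switches on 2-cell genes. It was at 99.4 ± 29 CPM against 2 counts in all tbGFP-negative cells, a ratio of 585 with a 95% counting interval of 162 to 4840. Tdpoz3 (ENSMUSG00000058005.3, chromosome 3, 93826020 to 93827117) had no counts in tbGFP-negative cells and was at least 3130-fold higher in tbGFP-positive cells, at 817 ± 57.6 CPM. Also without counts in tbGFP-negative cells were the pseudogene AA623943 (at least 2660-fold higher), the retinol dehydrogenase gene Rdh1 (at least 1740-fold), the deubiquitinase gene Usp17lc (at least 1560-fold), the netrin receptor gene Dcc (at least 1410-fold), Tcstv3 (at least 364-fold) and Zfp352 (at least 156-fold). Zscan4, Tdpoz, Usp17l, Tcstv and Gm8300-like genes have near-identical copies that share reads, so how their counts divide among copies is uncertain.

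Of 37 tested members of the 2-cell list, 36 were higher in tbGFP-positive cells at 0 h, as were 36 when adjusted over the list alone. Their median log2 fold change was 10.3, or 9.09 with members absent from a group set at their bound (camera adjusted p = 1.73e-190, and adjusted p = 0.000211 with an estimated correlation). The exception was Zfp750 (-0.08, adjusted p = 1). The cells had been sorted on a reporter of this program, so the direction follows the sort. Single genes of stress responses were also higher: the inducible Hsp70 genes Hspa1a (4.66 ± 0.46, adjusted p = 2.52e-06) and Hspa1b (4.24 ± 0.28), the antiproliferative p53 target Btg2 (2.20 ± 0.28), the kinase gene Plk2 (2.35 ± 0.50), Fos (1.56 ± 0.37) and Jun (1.61 ± 0.31). These 6 were chosen after their values were seen, and the lists that hold them did not pass. Of 12 heat-shock genes 2 were higher (camera adjusted p = 0.534), of 22 p53 targets 2 were higher and 1 lower (camera adjusted p = 0.871), and of 15 immediate-early genes 3 were higher (camera adjusted p = 0.871). The numbers were the same when adjusted over the list alone. The core pluripotency factor genes Pou5f1 (1000 ± 308 against 1290 ± 119 CPM, adjusted p = 0.613) and Sox2 (442 ± 71.1 against 441 ± 51.5 CPM, adjusted p = 1) did not pass. Nanog was higher (42.4 ± 3.07 against 12.7 ± 1.11 CPM, adjusted p = 0.0139). Lower in tbGFP-positive cells were the cholesterol acyltransferase gene Soat2 (1 count; ratio 42, interval 7.21 to 1690) and the chloride channel gene Best1 (2 counts; ratio 40.4, interval 10.9 to 338). Mcmdc2 (-2.74 ± 0.75), Adam1a (-2.36 ± 0.68) and the noncoding AV205837 (-1.65 ± 0.29) were also lower.

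At 0 h 1291 genes were higher and 87 lower in tbGFP-positive cells. The split rested on the scaling: 1080 were higher and 620 lower with upper-quartile factors, and 1078 and 812 with library totals alone. Without either tbGFP-negative library at 0 h, 912 (replicate 1) and 809 (replicate 2) genes were called. Without either tbGFP-positive library at 6 h, which takes no part in the contrast but adds to the shared estimate of spread, 2489 and 2462 were called, and 2455 without both. Among the 17 called genes that the naming rule picked, 12 kept their call in every alternative fit that held them, and Soat2, Best1, Mcmdc2, Adam1a and Nanog lost it in at least 1 (adjusted p up to 0.0657, 0.181, 0.252, 0.275 and 0.152).

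**Figure D2:**
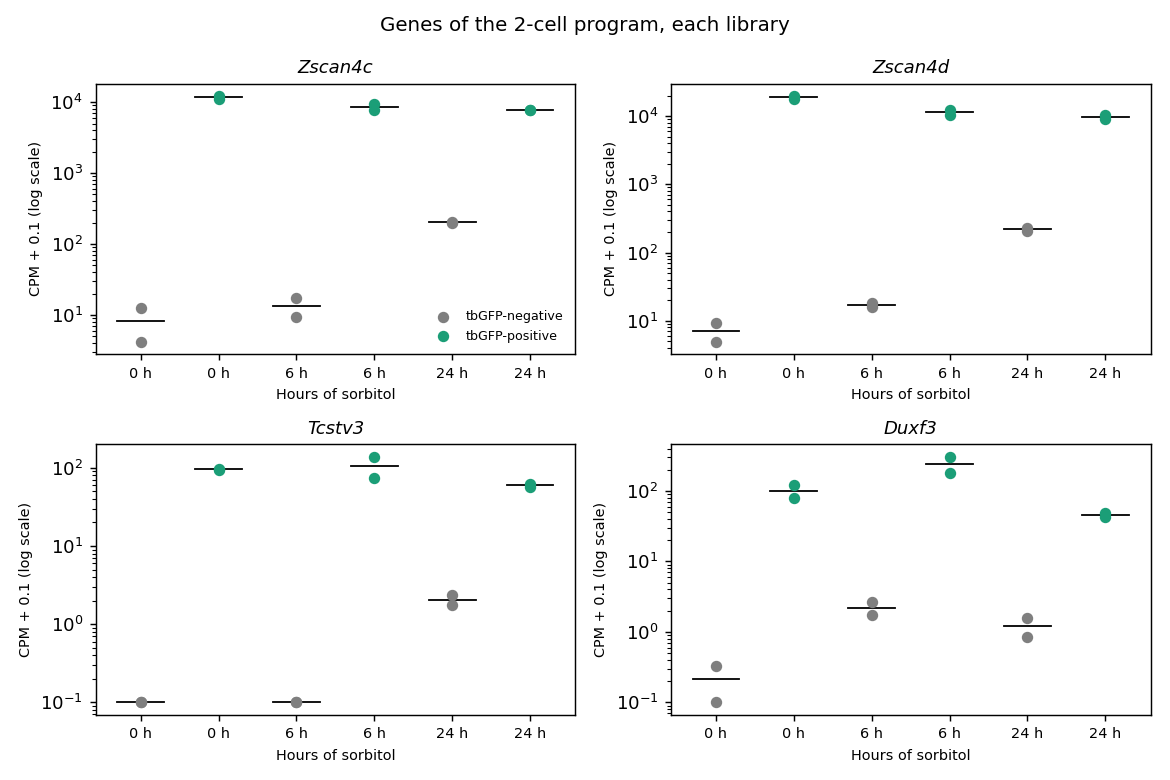
CPM plus a small constant (log axis) of 2-cell genes in each library, by hours of sorbitol and sorted fraction, with 1 point per library and a line at each group mean. Zscan4d stood near 219 CPM in tbGFP-negative cells at 24 h, between its level in tbGFP-negative cells at 0 h (6.97 CPM) and in tbGFP-positive cells at 24 h (9790 CPM).

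At 6 h of sorbitol the same 2-cell genes still set the fractions apart. Zscan4d was at 11400 ± 1590 against 16.9 ± 1.9 CPM (log2 fold change 9.38 ± 0.25, adjusted p = 1.27e-12), Zscan4c at 8620 ± 1230 against 13.3 ± 5.87 CPM and Duxf3 at 244 ± 88.8 against 2.09 ± 0.603 CPM. The 5 increases that the naming rule picked by fitted fold change were of genes without counts in tbGFP-negative cells, for which only bounds are given: Slfn2, of the Schlafen family, was at least 451-fold higher, Tcstv3 at least 381-fold, Popdc3 at least 374-fold, the olfactory receptor gene Olfr787 at least 343-fold, and AF067061 at least 290-fold. Zfp352, from the panel, also had no counts there and was at least 124-fold higher. Of the 37 members of the 2-cell list, 36 were higher, and 36 when adjusted over the list alone (median 8.83, or 8.53 with bounds, camera adjusted p = 8.76e-161, and adjusted p = 2.96e-05 with an estimated correlation). Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, was lower in tbGFP-positive cells (168 ± 47.9 against 377 ± 31.1 CPM, -1.16 ± 0.19, adjusted p = 0.000792), as was the taurine transporter gene Slc6a6 (245 ± 29.7 against 407 ± 47.5 CPM, adjusted p = 0.0127). The p53 target list was lower as a set (camera adjusted p = 0.026), which was lost with an estimated correlation (adjusted p = 0.847). Only Rps27l passed of its 22 tested members, and it alone when adjusted over the list alone. It had no counts in tbGFP-positive cells and was at least 24.5-fold lower. With upper-quartile factors 8 of the 22 were lower, and the list's median moved from -0.82 to -1.12. Bbc3 did not pass (-1.74 ± 0.57, adjusted p = 0.0624). Without replicate 1 of the tbGFP-positive cells at 6 h the list's adjusted p was 0.431.

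In this comparison 1342 genes were higher and 1012 lower in tbGFP-positive cells. Of the lower genes, 404 (39.9%) had no counts in either tbGFP-positive library, the libraries in which the fewest genes were detected. The 5 decreases picked by the naming rule were among them, and had group means of 8.39 to 12.4 CPM in tbGFP-negative cells: Wrap73 (at least 42.7-fold lower), Cnbp (at least 33.8-fold), Bicd2 (at least 31.3-fold), Mthfsd (at least 29.4-fold) and Yars2 (at least 29-fold). With only the 4 libraries at 6 h in the fit, 587 genes were higher and 22 lower, 609 in all. That fit ended the calls of the 5 genes just named and of Rps27l (adjusted p = 0.116), Hmox1 (adjusted p = 0.118) and Slc6a6 (adjusted p = 0.181). With upper-quartile factors 1182 were higher and 2454 lower. Without a tbGFP-negative library at 6 h, 1083 (replicate 1) and 1138 (replicate 2) genes were called, and without a tbGFP-positive library at 6 h 4226 and 5350.

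At 24 h of sorbitol, 36 of the 37 members of the 2-cell list were again higher in tbGFP-positive cells, and 36 when adjusted over the list alone, with a smaller median log2 fold change of 5.37 (camera adjusted p = 6.57e-161, and adjusted p = 8.53e-05 with an estimated correlation). Zscan4d was at 9790 ± 929 CPM in tbGFP-positive and 219 ± 19.9 CPM in tbGFP-negative cells (5.48 ± 0.21, adjusted p = 1.95e-10). Gm8300, of the Eif1a-like family of translation factor genes, was at 5560 ± 237 against 135 ± 13.2 CPM, and Duxf3 at 45.2 ± 4.36 against 1.1 ± 0.486 CPM. Genes without counts in tbGFP-negative cells included AF067061 (at least 166-fold higher), the sodium-proton exchanger gene Slc9a9 (at least 131-fold), the microRNA gene CAAA01098150.1 (at least 90.8-fold), the vomeronasal receptor gene Vmn2r52 (at least 63.3-fold) and the keratin-associated protein gene Krtap4-13 (at least 58.6-fold). Lower in tbGFP-positive cells were Lifr, the receptor for leukemia inhibitory factor (160 ± 0.701 against 322 ± 12 CPM, -1.01 ± 0.19, adjusted p = 0.00212), and Zfp57, a zinc finger gene that keeps methylation at imprinted loci (100 ± 22.7 against 215 ± 22 CPM, -1.10 ± 0.23). The RNA methyltransferase gene Nsun2 (-1.27 ± 0.33), the activin subunit gene Inhbb (-1.17 ± 0.32) and AV205837 (-1.15 ± 0.29) were lower too. All 5 lost their call in at least 2 alternative fits, with adjusted p up to 0.0549 for Lifr, 0.58 for Zfp57, 0.34 for Nsun2, 0.414 for Inhbb and 0.294 for AV205837. Hmox1 did not pass (0.67 ± 0.20, adjusted p = 0.0665).

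At 24 h 1037 genes were higher and 22 lower, or 884 higher and 424 lower with library totals alone. Of the 1037, 938 were also higher at 0 h, where 69.1 would be shared by independent lists, and 7 genes were lower at both times, against 0.0987. The 0 h and 24 h comparisons share no library, and across genes, which are not independent, their fold changes correlated with Pearson r = 0.706 and Spearman rho = 0.458. Without a tbGFP-positive library at 6 h, 1775 (replicate 1) and 1760 (replicate 2) genes were called, 1742 without both, and 2257 with only the libraries at 24 h.

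**Figure D3:**
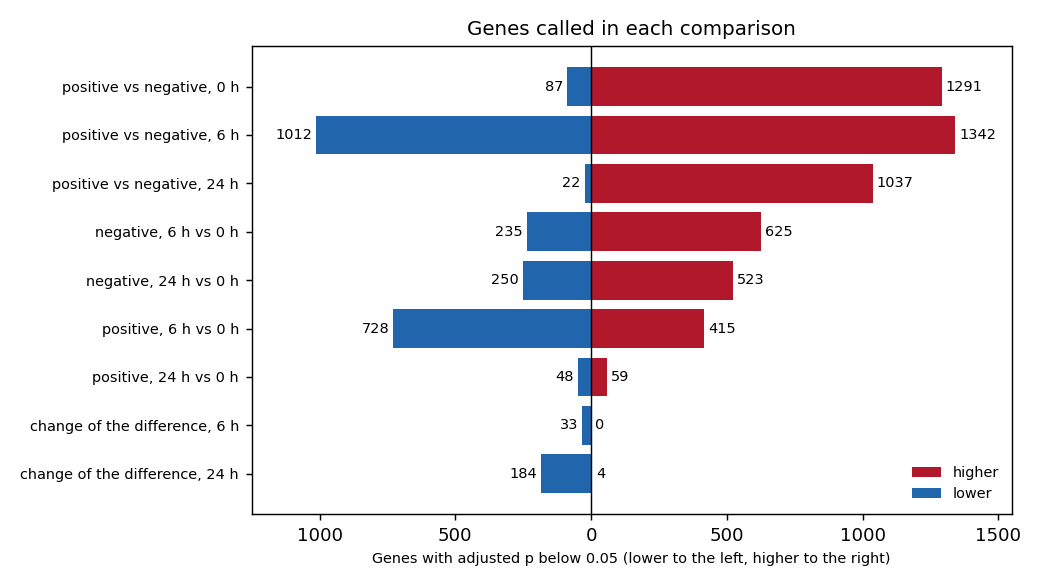
Number of genes called higher (bars to the right) and lower (bars to the left), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Bars are shown for the 7 comparisons between groups and the 2 interactions. The largest number of lower genes, 1012, was in tbGFP-positive against tbGFP-negative cells at 6 h.

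In tbGFP-negative cells at 6 h of sorbitol, 4 of 14 osmotic genes, 12 of 22 p53 targets and 4 of 12 heat-shock genes were higher than at 0 h. With an estimated correlation the p53 and heat-shock lists did not pass (adjusted p = 0.0656 and 0.123). Slc5a3, the sodium/myo-inositol cotransporter gene (ENSMUSG00000089774.2, chromosome 16, 92058322 to 92087473), rose from 26.9 ± 1.62 to 340 ± 27.9 CPM (3.65 ± 0.25, adjusted p = 1.72e-06). The aldose reductase gene Akr1b3 rose from 29.4 ± 4.65 to 61.7 ± 5.66 CPM (1.06 ± 0.23, adjusted p = 0.0173), and the amino acid transporter gene Slc38a2 also rose (1.86 ± 0.17). The cell cycle inhibitor gene Cdkn1a rose from 0.341 ± 0.482 to 34.4 ± 3.76 CPM (6.11 ± 0.94, adjusted p = 0.00171). Mdm2, which encodes the ubiquitin ligase of p53, rose from 9.43 ± 2.25 to 102 ± 2.01 CPM (3.40 ± 0.48), and Plk2 from 29.3 ± 2.89 to 2100 ± 87.2 CPM (6.15 ± 0.58). Hspa1a rose from 1.71 ± 0.309 to 52.4 ± 5.84 CPM and Hspa1b from 6.76 ± 1.53 to 102 ± 2.24 CPM. The antioxidant gene Hmox1 rose from 168 ± 12.5 to 377 ± 31.1 CPM (1.17 ± 0.20, adjusted p = 0.00304). Nfat5, the transcription factor of the osmotic response, was at 2.62 ± 2.23 against 2.22 ± 1.03 CPM (adjusted p = 0.992), and Slc6a6 at 407 ± 47.5 against 394 ± 11.5 CPM (adjusted p = 0.967).

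By list, 12 of 22 tested p53 targets rose, and 19 when adjusted over the list alone, and all 22 log2 fold changes were positive (median 2.05, camera adjusted p = 9.84e-24, and adjusted p = 0.0656 with an estimated correlation). Beyond those above, they included the cell death gene Bbc3 (3.41 ± 0.63), Trp53inp1 (2.60 ± 0.64) and Btg2 (68.7 ± 6.29 to 466 ± 43 CPM). Of 14 osmotic genes, 4 rose, and 4 when adjusted over the list alone: Slc5a3, Akr1b3, Slc38a2 and Hspa1b (camera adjusted p = 6.62e-05, and adjusted p = 0.0426 with an estimated correlation). The osmotic median was 0.02, and -0.08 with library totals alone, so the list's call rested on few members. Of 12 heat-shock genes, 4 rose, and 5 when adjusted over the list alone: Hspa1a, Hspa1b, Hsp90ab1 (0.80 ± 0.16) and Hspd1 (0.49 ± 0.13; list camera adjusted p = 1.64e-05, and adjusted p = 0.123 with an estimated correlation). With library totals alone 2 of the 12 rose, and their median moved from 0.42 to 0.08. Hspa1b stands in both the osmotic and the heat-shock list. Of 17 ribosome biogenesis genes, 3 rose (1 with library totals alone), and 7 when adjusted over the list alone. They were the nucleolin gene Ncl (612 ± 50.2 to 1720 ± 92.7 CPM), the polymerase I factor gene Rrn3 (1420 ± 86.7 to 2350 ± 122 CPM) and Npm1 (0.97 ± 0.21; list camera adjusted p = 0.00239, and adjusted p = 0.275 with an estimated correlation). Of 14 genes of the formative and primed state, the later state of pluripotency, 3 fell, and 3 when adjusted over the list alone. They were Zic2 (103 ± 15 to 36.5 ± 8.68 CPM), Foxd3 (82.3 ± 6.66 to 15.5 ± 3.39 CPM) and Zic5 (-1.43 ± 0.32; list camera adjusted p = 0.00417, and adjusted p = 0.275 with an estimated correlation).

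The 2-cell list also rose in tbGFP-negative cells at 6 h: 11 of 37 members were higher (7 with library totals alone), and 18 when adjusted over the list alone (median 1.59, or 1.31 with bounds, camera adjusted p = 6.93e-09, and adjusted p = 0.0426 with an estimated correlation). Ddit4l, an inhibitor of mTOR signalling, rose from 7.12 ± 1.55 to 71.2 ± 10.8 CPM (3.38 ± 0.25, adjusted p = 2.52e-06). Gm8300 rose from 3.41 ± 1.12 to 11.4 ± 1.43 CPM and Zscan4d from 6.97 ± 2.99 to 16.9 ± 1.9 CPM (1.17 ± 0.21, adjusted p = 0.00519). Duxf3 rose from 2 counts to 2.09 ± 0.603 CPM, a ratio of 12.3 with an interval of 3.03 to 107 (adjusted p = 0.0201). Zscan4c did not pass (0.54 ± 0.33, adjusted p = 0.451), and Zfp352 and Tcstv3 had no counts at either time. Carry-over of tbGFP-positive cells into the negative sort was not tested at 6 h. Atr, the kinase gene named in the title of the series, was lower (2.09 ± 0.603 against 11.9 ± 1.58 CPM, -2.50 ± 0.64, adjusted p = 0.0362). Its counts were spread over 13 transcripts, the most counted of which held 28%, and its call was lost when transcripts were tested one by one (adjusted p = 0.666). It was also lost without any of 10 of the 12 libraries, with adjusted p-values of 0.0541 to 0.281. Chek1 did not pass (adjusted p = 0.701).

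In all, 625 genes were higher and 235 lower at 6 h in tbGFP-negative cells. The split was 505 and 324 with DESeq2 size factors and 339 and 571 with library totals alone. The libraries compared differed in make-up too. The noncoding gene Rn7sk took 6.02% and 5.99% of counts at 6 h, against 3.47% and 3.49% at 0 h. Protein-coding genes took 75.68% and 75.8%, against 77.9% and 80.74%. Genes without counts at 0 h included the small nucleolar RNA gene Snord116l16 (at least 287-fold higher), the myosin gene Myh15 (at least 95.6-fold), the cytochrome P450 gene Cyp2c65 (at least 92.6-fold), the cell cycle regulator gene Rgcc (at least 76-fold) and the processed pseudogene CT009755.2 (at least 54.5-fold). The decreases picked by the naming rule were of Xlr3a (-4.39 ± 0.75), Trim26 (-4.33 ± 0.91), Mum1 (-3.75 ± 0.68), Ccdc77 (-3.61 ± 0.61) and the glutamine transporter gene Slc1a5 (-3.60 ± 0.72). DESeq2 called 1417 genes, and a fit of only the 4 libraries compared called 3944. Calls fell to 226 and 152 without replicates 1 and 2 at 0 h and to 207 and 234 without those at 6 h, and rose to 2532 and 2502 without replicates 1 and 2 of the tbGFP-positive cells at 6 h, or 2543 without both. Of the 28 called genes picked by the naming rule, 9 kept their call in every alternative fit: Slc5a3, Mdm2, Plk2, Btg2, Hspa1a, Hspa1b, Ncl, Ddit4l and Gm8300. Among the rest, Akr1b3 lost its call in 9 of 24 alternative fits (adjusted p from 0.0502 to 0.783), Hmox1 in 2 (up to 0.102), Zscan4d in 3 (up to 0.108), and Duxf3 in 4 (up to 0.233). The call was also lost for Foxd3 in 4 (up to 0.173), Zic2 in 3 (up to 0.134), Rrn3 in 6 (up to 0.232) and Cdkn1a in 1 (0.103).

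**Figure D4:**
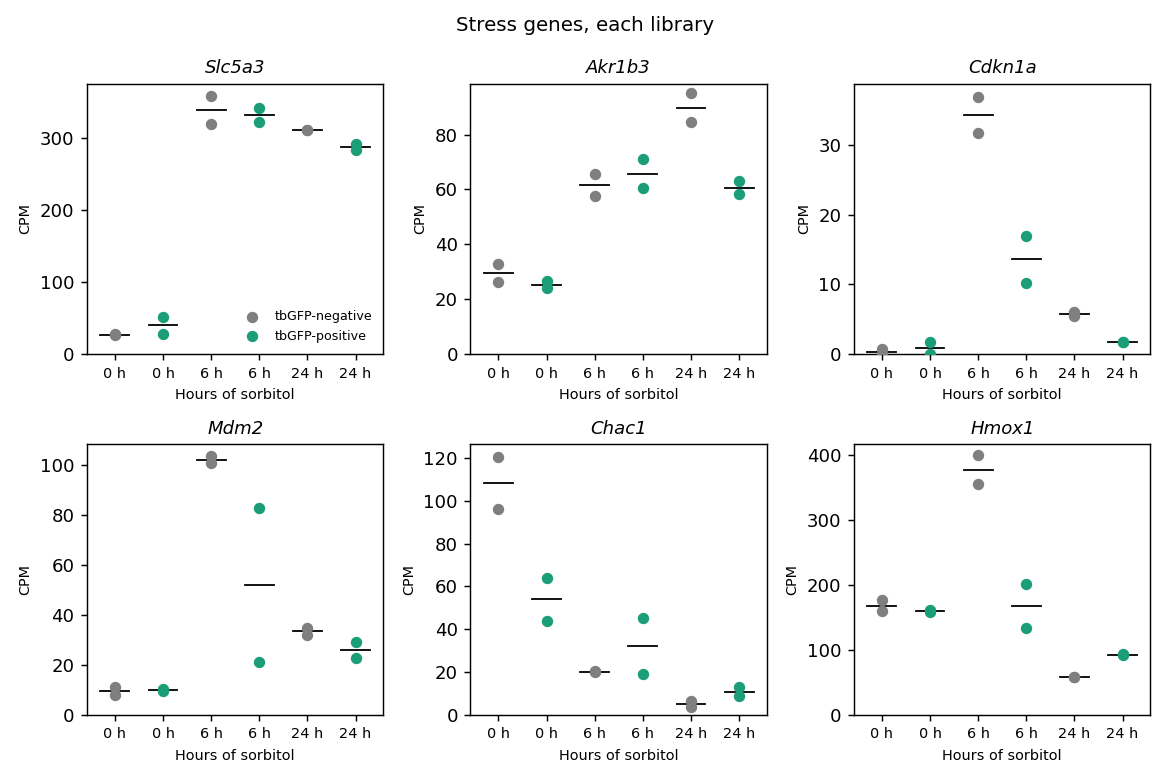
CPM (linear axis) of stress genes in each library, by hours of sorbitol and sorted fraction, with 1 point per library and a line at each group mean. Slc5a3 was near 300 CPM at 6 h and 24 h in both fractions, and Cdkn1a was highest at 6 h in tbGFP-negative cells (34.4 CPM).

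After 24 h in tbGFP-negative cells, the 2-cell list stood higher than at 0 h. Of its 37 members, 26 rose, and 30 when adjusted over the list alone (median 4.65, or 3.90 with bounds, camera adjusted p = 1.18e-101, and adjusted p = 0.000256 with an estimated correlation). Zscan4d rose from 6.97 ± 2.99 to 219 ± 19.9 CPM (4.85 ± 0.22, adjusted p = 7.52e-09), Zscan4c from 8.24 ± 5.85 to 202 ± 7.01 CPM (4.44 ± 0.33) and Gm8300 from 3.41 ± 1.12 to 135 ± 13.2 CPM (5.18 ± 0.20). Absent at 0 h, Tdpoz3 rose at least 138-fold to 36.1 ± 3.67 CPM, Usp17lc at least 30.8-fold to 8.05 ± 1.34 CPM, Tcstv3 at least 7.51-fold and Zfp352 at least 3.86-fold. Zfp352 rested on 6 and 11 counts at 24 h and lost its call without any 1 of 10 of the 12 libraries, with adjusted p from 0.051 to 0.527. Duxf3 did not pass (ratio 6.54, interval 1.59 to 57.7, adjusted p = 0.123). The tbGFP-negative libraries at 24 h also stood apart in make-up. Transcripts annotated as retained introns took 4.44% and 4.51% of their counts, against 2.3% to 3.48% in the other 10 libraries, and the noncoding gene Gm26917 1.62% and 1.7%, against 2.25% to 5.72%. At equal depth they showed 22870 and 22748 genes, against 18674 and 20740 in tbGFP-negative cells at 0 h, so the changes at 24 h are between libraries that differ in these too.

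At 24 h 3 of 14 osmotic genes were higher and 1 lower than at 0 h, and 6 of 16 targets of ATF4, the transcription factor of the integrated stress response, were lower. Slc5a3 was at 311 ± 0.355 CPM (3.53 ± 0.25, adjusted p = 5.65e-07), Akr1b3 at 89.8 ± 7.45 CPM (1.60 ± 0.24) and Hspa1b at 35.6 ± 1.9 CPM (2.45 ± 0.27). Besides these 3, which rose, the cystine transporter gene Slc7a11 fell, and 8 of the list rose and 1 fell when adjusted over the list alone (camera adjusted p = 4.06e-06, and adjusted p = 0.0218 with an estimated correlation). Of the ATF4 targets, 6 fell and 1 rose when adjusted over the list alone (median -1.67, camera adjusted p = 5.49e-12, and adjusted p = 0.0048 with an estimated correlation). The 6 called over all genes were the glutathione-degrading enzyme gene Chac1 (109 ± 17.1 to 4.99 ± 1.86 CPM, -4.42 ± 0.44, adjusted p = 2.3e-05), the serine synthesis genes Phgdh (243 ± 3.35 to 66 ± 1.29 CPM) and Psat1 (-1.88 ± 0.31), and Trib3, Mthfd2 and Slc7a11. Slc7a11 (10.6 ± 3.96 to 1.8 ± 0.501 CPM) and Hmox1 (168 ± 12.5 to 58 ± 0.696 CPM, -1.53 ± 0.20, adjusted p = 0.000236) fell. They were the 2 of 19 NRF2 antioxidant targets that did, and 2 fell when adjusted over the list alone (camera adjusted p = 0.00206, and adjusted p = 0.119 with an estimated correlation). Slc7a11 lost its call in 11 of 24 alternative fits, 8 of them without 1 library. Among these was each fit without a tbGFP-negative library at 0 h or 24 h. Of the p53 targets, 5 of 22 rose (3 with upper-quartile factors), and 9 when adjusted over the list alone. They were Btg2 (389 ± 4.45 CPM), Perp (17.1 ± 0.992 to 182 ± 10.4 CPM), Plk2, Cdkn1a (5.67 ± 0.414 CPM, adjusted p = 0.0432) and Mdm2 (33.4 ± 1.8 CPM; list camera adjusted p = 3.64e-05, and adjusted p = 0.292 with an estimated correlation). Without either tbGFP-negative library at 0 h, the adjusted p of Cdkn1a was 0.282 (replicate 1) and 0.178 (replicate 2), and that of Mdm2 0.354 and 0.281.

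Further lists passed at 24 h in tbGFP-negative cells. Of 14 formative and primed genes 3 fell, and 3 when adjusted over the list alone. They were Zic2 (to 15 ± 0.308 CPM, -2.78 ± 0.31), Zic5 (68 ± 1.03 to 9.9 ± 3.76 CPM) and Utf1 (-0.97 ± 0.23; list camera adjusted p = 1.02e-05, and adjusted p = 0.0857 with an estimated correlation). Sox2 rose (441 ± 51.5 to 711 ± 17.3 CPM, adjusted p = 0.0336) and lost its call with DESeq2 size factors (adjusted p = 0.0648) and upper-quartile factors (adjusted p = 0.195). Pou5f1 did not pass (1290 ± 119 to 679 ± 1.18 CPM, adjusted p = 0.0846). The next 5 lists each passed with 1 member called, which was the count adjusted over the list alone too, except where given. Of 11 mitochondrial mRNAs mt-Cytb fell (camera adjusted p = 0.00865, and adjusted p = 0.501 with an estimated correlation). Of 75 ribosomal protein genes Rpl10l fell (0.0249 and 0.0857, in the same order), and of 21 S-phase genes Rrm2 fell, with 2 adjusted over the list alone (0.0205 and 0.109). Of 61 replication histone genes Hist3h2a rose, while the list was lower (median -0.28, 0.0149 and 0.76). Of 8 trophectoderm markers the keratin gene Krt8 rose (17.7 ± 1.9 to 37.9 ± 3.44 CPM), with 2 adjusted over the list alone (0.0249 and 0.119), and Krt19 did not pass (3.25 ± 0.87, adjusted p = 0.0506). Without replicate 1 of the tbGFP-negative cells at 0 h, the adjusted p was 0.0799 for the mitochondrial and 0.66 for the histone list, and without replicate 2 it was 0.104 for the trophectoderm list.

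In all, 523 genes were higher and 250 lower at 24 h in tbGFP-negative cells, and 412 and 408 with upper-quartile factors. The median log2 fold change of all genes was 0.23, so small changes are relative to it; it was 0.05 with upper-quartile factors. Outside the lists, Asb12 (at least 41.8-fold) and the glutamate receptor gene Grin2a (at least 33-fold) were higher, as was Snord116l16 (at least 38.2-fold), whose libraries differed widely (9.98 ± 12.5 CPM). The growth factor gene Fgf15 (38.4 ± 1.97 to 2.99 ± 0.431 CPM), the cyclin gene Ccnd2 (-3.60 ± 0.61), Ubap1l (-3.89 ± 0.57) and the antisense RNA Vax2os (-4.20 ± 0.89) fell. DESeq2 called 1312 genes and a fit of the 4 libraries alone 3247. Without replicates 1 and 2 at 0 h 350 and 270 were called, without those at 24 h 356 and 379, and without the tbGFP-positive libraries at 6 h 1883 and 1876, or 1923 without both. Here 15 of the 32 called genes picked by the naming rule kept their call in every alternative fit, among them Slc5a3, Chac1, Phgdh, Hmox1, Btg2, Hspa1b, Zic2, Zic5, Zscan4c, Zscan4d, Gm8300, Tdpoz3 and Usp17lc. Sox2 and Mdm2 each lost it in 15 alternative fits (adjusted p up to 0.587 and 0.439), and Cdkn1a in 13 (up to 0.282). So did Krt8 in 10 (up to 0.436), mt-Cytb in 6 (up to 0.282), Rrm2 in 5 (up to 0.126), Perp in 3 (up to 0.177) and, in 1 fit each, Akr1b3 (0.264), Tcstv3 (0.218) and Rpl10l (0.0579).

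In tbGFP-positive cells at 6 h, Slc5a3 rose from 39.7 ± 17.3 to 332 ± 13.8 CPM (3.06 ± 0.24, adjusted p = 1.14e-05), Slc38a2 from 624 ± 98.6 to 2110 ± 514 CPM (1.76 ± 0.17) and Akr1b3 from 25.2 ± 1.74 to 65.7 ± 7.57 CPM (1.38 ± 0.24). These were the 3 of 14 osmotic genes that rose, with 7 when adjusted over the list alone (camera adjusted p = 5.13e-05, and adjusted p = 0.0658 with an estimated correlation). Of 22 p53 targets 5 rose, and 9 when adjusted over the list alone. They were Cdkn1a (0.862 ± 1.22 to 13.6 ± 4.78 CPM, adjusted p = 0.0195), Mdm2, Btg2, Zmat3 (6.07 ± 0.896 to 31.1 ± 0.841 CPM) and Plk2, whose 6 h libraries differed widely (1200 ± 1080 CPM). The p53 list passed (camera adjusted p = 1.1e-05), which was lost with an estimated correlation (adjusted p = 0.637) and without replicate 2 of the tbGFP-positive cells at 6 h (adjusted p = 0.425). Of 15 immediate-early genes, Jun, Ier3, Klf6 and Gadd45b rose and Dusp6 fell, and 6 rose and 2 fell when adjusted over the list alone. Ier3 rose from 31.8 ± 13.2 to 87.8 ± 5.57 CPM and Klf6 from 109 ± 7.15 to 230 ± 33 CPM (list camera adjusted p = 0.00142, and adjusted p = 0.422 with an estimated correlation). Without replicate 2 of the tbGFP-positive cells at 0 h the adjusted p of that list was 0.0585. Duxf3 rose from 99.4 ± 29 to 244 ± 88.8 CPM (1.30 ± 0.31, adjusted p = 0.0254) and Zscan4d fell from 19000 ± 1170 to 11400 ± 1590 CPM (-0.74 ± 0.17, adjusted p = 0.0233). Across the 2-cell list 2 members rose and 4 fell, and the list did not pass (camera adjusted p = 0.931). When adjusted over the list alone, 3 rose and 5 fell. Nanog fell from 42.4 ± 3.07 to 13 ± 7.7 CPM (adjusted p = 0.0253).

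At 6 h in tbGFP-positive cells 415 genes were higher and 728 lower, with the same sparse libraries as above. Without counts at 0 h were the innate immune receptor gene Tlr13 (at least 62-fold higher), Cyp2c65 (at least 44.5-fold), Lrit1 (at least 38.5-fold), the integrin gene Itgax (at least 37.1-fold) and the Wnt co-receptor gene Lgr5 (at least 36.7-fold). Without counts at 6 h were the helicase gene Mcm9 (at least 43.9-fold lower), Arhgef18 (at least 40.8-fold), the autophagy receptor gene Nbr1 (at least 39.8-fold), the ciliary gene Cep290 (at least 36-fold) and Cnbp (at least 33.1-fold). A fit of only the 4 libraries called 4 genes, all higher, and none of the 22 called genes picked by the naming rule; in it the adjusted p was 0.0558 for Slc5a3, 0.0744 for Slc38a2, 0.359 for Akr1b3, 0.452 for Cdkn1a, 0.332 for Duxf3 and 0.309 for Zscan4d. DESeq2 called 2419 genes. Among fits without 1 library, 9 of 12 counts moved by over 1.5 times. For the tbGFP-negative cells they were 698 without replicate 1 at 0 h, and 696 and 695 without replicates 1 and 2 at 24 h. For the tbGFP-positive cells they were 731 and 483 at 0 h, 4008 and 3773 at 6 h, and 603 and 702 at 24 h.

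In tbGFP-positive cells at 24 h, Slc5a3 was at 288 ± 5.92 CPM against 39.7 ± 17.3 CPM at 0 h (2.85 ± 0.24, adjusted p = 0.000106), Slc38a2 at 1270 ± 26.3 against 624 ± 98.6 CPM and Akr1b3 at 60.7 ± 3.33 against 25.2 ± 1.74 CPM. Again 3 of 14 osmotic genes rose, and 6 when adjusted over the list alone (camera adjusted p = 3.28e-06, and adjusted p = 0.033 with an estimated correlation). Chac1 fell from 54 ± 14.1 to 10.8 ± 3.24 CPM (-2.31 ± 0.41, adjusted p = 0.0193). It was the only one of 16 ATF4 targets called, with 4 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.000342, and adjusted p = 0.0783 with an estimated correlation). Zscan4d fell to 9790 ± 929 CPM (-0.95 ± 0.17, adjusted p = 0.0208) and Spz1, a sperm transcription factor gene, did not pass (169 ± 3.98 to 88.4 ± 6.33 CPM, adjusted p = 0.115). Only Zscan4d was called of the 37 members of the 2-cell list, with 4 higher and 5 lower when adjusted over the list alone. The list's median was -0.14 (camera adjusted p = 0.0215, and adjusted p = 0.38 with an estimated correlation), and without replicate 2 of the tbGFP-positive cells at 24 h the adjusted p was 0.224. The fibroblast growth factor gene Fgf4 fell from 672 ± 91 to 292 ± 53.5 CPM. It was the only one called of 22 naive pluripotency genes, with 3 when adjusted over the list alone (camera adjusted p = 0.00518, and adjusted p = 0.38 with an estimated correlation). Without replicate 1 of the tbGFP-positive cells at 0 h the list's adjusted p was 0.0566.

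Further lists passed in tbGFP-positive cells at 24 h with at most 1 gene called. None of 22 p53 targets was called by edgeR and 1 was when adjusted over the list alone, while 17 of their log2 fold changes were positive (camera adjusted p = 0.000221, and adjusted p = 0.384 with an estimated correlation). Perp was nearest, from 22.9 ± 10.1 to 181 ± 1.9 CPM (adjusted p = 0.0532). Of 21 S-phase genes the helicase gene Mcm4 fell, with 2 adjusted over the list alone (0.0474 and 0.292, in the same order). No gene was called of 15 immediate-early genes, with 1 adjusted over the list alone (higher as a list, 0.0393 and 0.38). The same was so of 11 primitive endoderm markers, with 1 adjusted over the list alone (higher, 0.0375 and 0.292), and of 11 mitochondrial mRNAs, with 0 adjusted over the list alone (lower, 0.0393 and 0.641). Leaving out 1 library raised the adjusted p above the threshold for the S-phase list (0.183 without replicate 2 of the tbGFP-positive cells at 24 h), the primitive endoderm list (0.294 without replicate 1 of those at 0 h) and, without replicate 2 of those at 0 h, the immediate-early (0.563) and mitochondrial lists (0.563).

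At 24 h 59 genes were higher and 48 lower in tbGFP-positive cells, or 68 and 28 with library totals alone. The chemokine gene Ccl8 had no counts at 0 h and was at least 49.8-fold higher, and Mrps6, which overlaps Slc5a3 in the annotation, rose from 2 counts (ratio 48.5, interval 13.2 to 405). The monooxygenase gene Moxd1 (5.48 ± 0.94), the mucin gene Muc1 (4 ± 0.8) and the lipoxygenase gene Alox12e (3.97 ± 0.48) also rose. The Hedgehog transcription factor gene Gli2 (86.4 ± 0.526 to 15.3 ± 6.53 CPM), Fgf15 (45.1 ± 3.97 to 8.42 ± 1.62 CPM), Zic5 (-1.98 ± 0.33) and Slc5a4b (-1.93 ± 0.40) fell. Of the 59 higher genes 49 were also higher at 24 h in tbGFP-negative cells, against 1.59 for independent lists, and 38 of the 48 lower genes were lower there, against 0.619; these 2 comparisons share no library. Another 5 genes higher in one fraction were lower in the other. Every fit without 1 library moved the count of 107 by over 1.5 times: 43 and 51 without replicates 1 and 2 of the tbGFP-negative cells at 0 h, 64 and 63 at 6 h and 51 and 52 at 24 h. Without replicates 1 and 2 of the tbGFP-positive cells it was 56 and 17 at 0 h, 928 and 888 at 6 h and 9 and 24 at 24 h. Without the whole 6 h tbGFP-positive group 913 were called, and DESeq2 called 496. Of the 16 called genes picked by the naming rule, Slc5a3 alone kept its call in every alternative fit; the highest adjusted p was 0.181 for Slc38a2, 0.361 for Akr1b3, 0.472 for Chac1, 0.48 for Zscan4d, 0.25 for Fgf4 and 0.617 for Mcm4. The shared count of 87 moved in every such fit too, from 8 without replicate 1 of the tbGFP-positive cells at 24 h to 538 without replicate 1 at 6 h.

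Whether the change from 0 h differed between the 2 fractions was tested as an interaction. The cells were sorted after the culture, so the interaction compares sorted fractions, not fixed populations of cells. At 24 h 184 genes had a negative interaction, a smaller change in tbGFP-positive than in tbGFP-negative cells on the signed log2 scale, and 4 a positive one. Of the 37 members of the 2-cell list 23 were among the 184, and 30 when adjusted over the list alone (median -4.66, camera adjusted p = 4.12e-155, and adjusted p = 2.49e-05 with an estimated correlation). For Zscan4d the interaction was -5.81 ± 0.27 (adjusted p = 1.73e-08). At 6 h no gene had a positive interaction by edgeR with TMM factors and 33 had a negative one. With DESeq2 size factors edgeR called 2 positive and 25 negative, and with library totals alone 6 and 18. With TMM factors 2586 genes had an unadjusted p under 0.05, and DESeq2 called 60 positive and 216 negative. The 33 included Ddit4l (-3.87 ± 0.32, adjusted p = 5.11e-05), Hspa1b (-3.32 ± 0.36) and Hspa1a (-4.17 ± 0.57), named after their values were seen. At 6 h the 2-cell list had 3 negative members (1 with library totals alone), and 15 when adjusted over the list alone (median -1.56, camera adjusted p = 4.78e-09, and adjusted p = 0.0484 with an estimated correlation). The heat-shock list had 2, and 4 when adjusted over the list alone (camera adjusted p = 0.00798, and adjusted p = 0.63 with an estimated correlation), though its median of -0.40 was 0.02 with library totals alone. Without replicate 2 of the tbGFP-positive cells at 6 h its adjusted p was 0.515. None of the p53 targets was called by edgeR at 6 h, and 3 were when adjusted over the list alone (camera adjusted p = 7.93e-05, and adjusted p = 0.63 with an estimated correlation). At 24 h the ATF4 targets (camera adjusted p = 0.00076, with 1 adjusted over the list alone) and the formative genes (0.0159, with 0 adjusted over the list alone) had a positive interaction as lists with no gene called by edgeR over all genes. Their lists had adjusted p = 0.0974 and 0.333 with an estimated correlation, and the formative list 0.118 without replicate 1 of the tbGFP-negative cells at 24 h. A different response of Slc5a3 was not shown at 6 h (-0.59, adjusted p = 0.442) or 24 h (-0.67, adjusted p = 0.943), nor of Cdkn1a (-2.25, adjusted p = 0.46, and -2.60, adjusted p = 1).

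Of the 24 lists, 8 passed in none of the 9 tests. The lowest camera adjusted p was 0.477 for 23 ATR and DNA repair genes, 0.477 for 24 repressors of the 2-cell program and chromatin factors, 0.0769 for 19 G2/M genes, and 0.0839 for 19 cholesterol synthesis genes. It was 0.231 for 17 glycolysis and hypoxia genes, 0.165 for 8 germline genes, 0.123 for 9 fibroblast markers and 0.256 for 5 mesoderm and ectoderm markers. Trim28 and Chaf1a, repressors of the 2-cell program, did not pass in any of the 7 comparisons between groups, nor did Nfat5, Srxn1 or Chek1. With protein-coding transcripts and by transcript, Chek1 was called lower in tbGFP-positive cells at 6 h, against tbGFP-negative cells and against 0 h.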

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

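In this part, the tests on reads shared between gene copies and on parts of the 70 genes below were chosen only after the result was seen. Adjusted p-values are from edgeR with Benjamini-Hochberg adjustment.

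The change with 24 h of sorbitol differed between the sorted fractions for 188 genes, 184 of them with a negative interaction. The most negative that the naming rule picked were Tdpoz3 (-9.42, adjusted p = 0.00642), Rdh1 (-9.28), AA623943 (-8.94), Usp17lc (-8.68) and Spz1 (-8.49). From the panel they included Tcstv3 (-7.24 ± 1.16), Zscan4d (-5.81 ± 0.27) and Zscan4c (-5.04 ± 0.42, adjusted p = 6.44e-06). Most of these genes had no counts in tbGFP-negative cells at 0 h, so these fitted values depend on a prior count. In tbGFP-negative cells Tdpoz3 was at 0 CPM at 0 h and 36.1 CPM at 24 h, and in tbGFP-positive cells at 817 and 2060 CPM. Positive interactions were found for Soat2 (6.81 ± 1.5), the imprinted noncoding gene Rian (1.32 ± 0.27) and Map1b (1.02 ± 0.19). Soat2 went from 0.0958 to 1.99 CPM in tbGFP-positive and from 5.03 to 0.691 CPM in tbGFP-negative cells. Its interaction was lost in 12 of 24 alternative fits, with adjusted p up to 0.224. The interactions of Rian and Map1b were lost in 8 of 23 and 4 of 24, those of Tdpoz3, AA623943 and Tcstv3 in 2, 1 and 1, and those of Rdh1, Usp17lc, Spz1, Zscan4c and Zscan4d in 0. Without replicate 2 of the tbGFP-negative cells at 0 h 75 genes were called, without replicate 1 or 2 of the tbGFP-positive cells at 6 h 326 and 320, and without replicate 2 of those at 24 h 120.

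The pattern behind these values was a rise of genes specific to tbGFP-positive cells in tbGFP-negative cells at 24 h. The summed mean CPM (TMM-scaled) of Zscan4a to Zscan4f in tbGFP-negative cells was 0.0479% of that in tbGFP-positive cells at 0 h, 0.15% at 6 h and 2.38% at 24 h. Carry-over of average tbGFP-positive cells into the negative sort would hold each gene at 1 fraction of its positive level. That fraction was examined in 70 genes. They had at most 3 counts in tbGFP-negative cells at 0 h and 6 h and at least 50 CPM in tbGFP-positive cells at 24 h. Their fractions varied by gene in a way shared by the 2 replicates (Spearman rho = 0.478, permutation p = 7e-05 with 100000 permutations across genes, which are not independent). This does not decide on carry-over, since the labels do not say that the 2 replicates were sorted apart. The fractions at 24 h also differed in make-up, which could shift the values by gene in both replicates. Retained introns took 4.44% and 4.51% of counts in tbGFP-negative cells and 2.61% and 3.04% in tbGFP-positive cells. The 70 had also to be called higher in tbGFP-positive cells at 0 h. In tbGFP-negative cells 42 of them were called higher at 24 h than at 0 h. Their low counts at 0 h left room for a rise only, so the 42 cannot count as a test of the rise. Of the 70, 59 counted, by symbol or gene type, as noncoding or as members of multi-copy families, whose copies can share reads. Among the other 11, of which 4 carry clone-based symbols (AC165294.1, AC125149.5, AC133103.5 and BC147527), rho was 0.482 (permutation p = 0.138), too few to decide alone, and among the 37 of the 70 with at least 100 CPM it was 0.636. Reads shared between copies are argued against as the whole cause by 39 protein-coding genes, chosen by their level at 6 h and in tbGFP-positive cells after families known by symbol as multi-copy were left out. Relatives by sequence were not searched for, and some of the 39, such as Slfn2, Zfp560 and Phf11a, belong to gene families. Clone-based symbols such as BB287469 and AW822073 stayed in. In tbGFP-negative cells the median log2 ratio of the 39, 24 h to 0 h with a floor of 3 counts per group, was 2.42 (quartiles 1.69 and 3.65). Of the 39, 28 were called higher and 0 lower. Some, such as Ccl3 (0 counts at 0 h) and Popdc3 (2), had room for little but a rise. Others had more counts at 0 h and rose, among them Arg2 (7 to 342 counts), Mecom (8 to 165), Tmem72 (14 to 215) and Spesp1 (35 to 231), named after their values were seen.

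Carry-over of cells near the sorting gate with a profile of their own, background that differs by gene, and weak 2-cell expression in tbGFP-negative cells after sorbitol may each lie behind the 0.478, and none of the 3 was tested. Their shares cannot be had from 2 libraries per group without cell counts or single-cell data.

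At 6 h the change with sorbitol differed between the fractions for 33 genes, all negative with TMM factors; 2 were positive and 25 negative with DESeq2 size factors, and 6 and 18 with library totals. Cep290 (-8.96, adjusted p = 0.0245), Nbr1 (-8.89), Cnbp (-8.15), Igsf21 (-8.02) and Mcm9 (-7.76) had no counts in either tbGFP-positive library at 6 h, so their values depend on a prior count. Zscan4d was at -1.91 ± 0.27 (adjusted p = 0.00939). Each of these 6 lost its call in at least 4 alternative fits, with adjusted p up to 0.561 for Cep290 and 0.0877 for Zscan4d. Without 1 library, 10 and 15 genes were called (tbGFP-negative, 0 h, replicates 1 and 2), 16 and 13 (tbGFP-positive, 0 h), 12 and 13 (tbGFP-negative, 6 h), 1207 and 2167 (tbGFP-positive, 6 h) and 18 (tbGFP-positive, 24 h, replicate 1).

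A wider pattern at 6 h, to which Cep290, Nbr1, Cnbp, Igsf21 and Mcm9 belonged, was the 1012 genes lower in tbGFP-positive than in tbGFP-negative cells. Their median log2 fold change was -3.08 at 6 h and -0.28 at 24 h, and 6 of them were called lower at 24 h. Depth is argued against: with all libraries thinned to 2305061 counts, 681 genes were still lower at 6 h, against 117 at 0 h and 22 at 24 h. Random loss of transcripts, as from little starting RNA, stays open. Of 12799 genes counted in the other 10 libraries, 1756 and 1540 were at 0 in the 2 tbGFP-positive libraries at 6 h, and 671 in both, against 519.6 expected within classes of abundance. The common odds ratio of 1.99 (interval 1.75 to 2.27) lay between the values set beforehand for loss at random and for loss of the same genes, so random loss and a lower level of these genes in tbGFP-positive cells at 6 h cannot be told apart here.

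The last pattern was the excess of higher over lower calls in tbGFP-positive cells at 0 h and 24 h. It rested in part on the scaling: the share of higher calls at 0 h was 93.7% with TMM factors and 57% with library totals, and at 24 h 97.9% and 67.6%. The median log2 fold change of all genes at 0 h moved from 0 to -0.41, and at 24 h from -0.05 to -0.48. A scaling that takes most genes as unchanged may therefore set the ratio, and without an added standard the true level of most transcripts between the fractions stays open, as does a real excess of raised genes.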

How the results depend on the processing

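The tests with library totals, by transcript, with protein-coding transcripts, with 1-transcript genes and without the 6 h tbGFP-positive group were chosen only after the results were seen. Adjusted p-values are from edgeR, DESeq2 or camera. All alternatives ran. The cause of the moves below was not tested.

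The 279 values of named genes gave 6647 alternative values: 5797 kept direction and side of the threshold, 514 lost the call, 167 gained one, 4 turned and 165 moved. The 4 were of Chek1, which was not called in the main fit of either comparison but was called lower in these alternatives. In tbGFP-positive against tbGFP-negative cells at 6 h it was -7.72 with protein-coding transcripts and -7.71 by transcript. In tbGFP-positive cells at 6 h against 0 h it was -6.87 and -6.73. A fold above 2 left all counts of calls within 1.5 times.

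Counts of called genes that moved by over 1.5 times follow. With upper-quartile factors 3636 genes differed between fractions at 6 h. DESeq2 gave 1417 and 1312 in tbGFP-negative cells at 6 h and 24 h, 2419 and 496 in tbGFP-positive cells, 276 for the 6 h interaction and 312 shared by the fractions at 24 h. Without a filter there were 1802 and 361 in tbGFP-positive cells at 6 h and 24 h, 276 and 312 for the interactions at 6 h and 24 h, and 232 shared. With only the groups compared, 609 and 2257 differed between fractions at 6 h and 24 h, 3944 and 3247 in tbGFP-negative cells at 6 h and 24 h, 4 in tbGFP-positive cells at 6 h, and 9 for the 6 h interaction.

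With protein-coding transcripts (9612 genes) 689, 1076 and 488 differed between fractions at 0, 6 and 24 h, 558 and 178 in tbGFP-positive cells at 6 h and 24 h, 20 and 100 for the interactions, 415 were shared between 0 h and 24 h and 145 between fractions. Among 8157 genes with 1 transcript 870 and 1336 differed between fractions at 0 h and 6 h, 236 and 336 in tbGFP-negative cells, 468 and 3 in tbGFP-positive cells, 15 for the 6 h interaction and 3 were shared between fractions. Without the 6 h tbGFP-positive group, 2455 and 1742 differed between fractions at 0 h and 24 h, 2543 and 1923 in tbGFP-negative cells, 913 in tbGFP-positive cells at 24 h and 321 for the 24 h interaction, and 544 were shared between fractions.

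With an estimated correlation 9 of 168 list tests passed, against 33. The 2-cell list in tbGFP-positive cells at 24 h then had adjusted p = 0.38, and 0.0557 with library totals. At 6 h, where it had not passed, it had 0.516 without a filter and 0.983 with the strict one.

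Without 1 library at a time, where a group of 1 is assumed to vary like the rest, 809 to 2489, 1083 to 5350 and 719 to 1775 genes differed between fractions at 0, 6 and 24 h, 152 to 2532 and 270 to 1883 in tbGFP-negative cells, 483 to 4008 and 9 to 928 in tbGFP-positive cells, and 10 to 2167 and 75 to 326 for the interactions. Shared between fractions were 8 to 538, and the 2-cell list in tbGFP-positive cells had adjusted p = 0.638 to 0.952 at 6 h and 0.0012 to 0.224 at 24 h. The highest counts came without a 6 h tbGFP-positive library, and 24 h tbGFP-positive replicate 2 was the one without which that list's 24 h call was lost.

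With the replicate number as a replicate block, 1281, 1946 and 1014 genes differed between fractions, 754 and 712 in tbGFP-negative cells, 771 and 95 in tbGFP-positive cells, and 32 and 180 for the interactions, all within 1.5 times. Deviations of same-numbered libraries correlated at -0.123 to 0.244 over 15 pairs of groups, 1 above 0.1. That 1 was of tbGFP-positive cells at 0 h and 24 h. No pairing common to the groups was seen, but weak correlations cannot show that the numbers mark nothing shared.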

Other observations

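In this part, all tests of gene families were chosen only after the results were seen. They are Fisher tests of family membership among called genes, adjusted with the Benjamini-Hochberg method over 98 tests, and genes of a family are not independent.

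At 6 h of sorbitol, zinc finger genes named Zfp were over-represented among lower genes. In tbGFP-negative cells 35 of 319 were lower (11% against 1.21% of all tested genes, adjusted p = 1.99e-21), and in tbGFP-positive cells 34 (10.7% against 3.76%, adjusted p = 1.17e-06). The 34 came from the sparse tbGFP-positive libraries at 6 h, and were 34, 34 and 31 with DESeq2 size factors, upper-quartile factors and library totals. An edgeR fit of only the 4 libraries compared called 0 lower genes of any kind there, while DESeq2 called 1509. Zfp57 fell by 3.14 ± 0.26 (log2) in tbGFP-negative and by 2.33 ± 0.25 in tbGFP-positive cells, and Zfp866 by 1.54 ± 0.24 in tbGFP-negative cells. The family's median in tbGFP-negative cells was -0.54, and -0.66, -0.59 and -0.88 with the other 3 scalings, so its direction did not turn. Its lower genes there numbered 46 with DESeq2 size factors, 36 with upper-quartile factors and 68 with library totals, with which all lower calls went from 235 to 571. Phosphatase genes of the Dusp family, which act on MAP kinases, were higher in tbGFP-negative cells at 6 h: Dusp2, Dusp4, Dusp5 and Dusp10, 4 of 16 with each of the 4 scalings (adjusted p = 0.0117). In tbGFP-positive cells at 6 h, Dusp2, Dusp4 and Dusp10 were higher (3 of 16, adjusted p = 0.029) and Dusp6 was lower.

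After 24 h in tbGFP-negative cells, 6 of 17 tubulin genes were lower (adjusted p = 1.17e-06; 5 with library totals), among them Tubb2b (-1.12 ± 0.16) and Tuba1b (-0.96 ± 0.14). So were 3 of 19 cytosolic aminoacyl-tRNA synthetase genes, Aars (-1.56 ± 0.16), Gars (-1.11 ± 0.15) and Yars (-1.23 ± 0.17). The adjusted p of that family was 0.0123, and 5 were lower with DESeq2 size factors or upper-quartile factors. In tbGFP-positive cells at 24 h, 2 tubulin genes (Tuba1a and Tubb2b, adjusted p = 0.0103) and 2 synthetase genes (Aars and Yars, adjusted p = 0.0109) were lower too. With library totals these numbers were 0 and 1. Before sorbitol, 4 of 5 genes of the imprinted Dlk1-Dio3 region were lower in tbGFP-positive cells, with each of the 4 scalings: Rtl1 (-1.57 ± 0.21), Rian (-1.15 ± 0.20), Meg3 (-1.13 ± 0.21) and Mirg (-1.33 ± 0.31; adjusted p = 9.24e-08 for the family). In tbGFP-negative cells at 6 h Rian rose (2.38 ± 0.20) while Rtl1 and Mirg fell. Of 90 olfactory and vomeronasal receptor genes, 15, 16 and 14 were higher in tbGFP-positive cells at 0, 6 and 24 h (adjusted p = 0.0103, 0.00679 and 0.00568). These were 16.7%, 17.8% and 15.6% of the family, against 6.66%, 6.92% and 5.35% of all tested genes. Pseudogenes made up 15.2% of tested genes and 23.5%, 23.8% and 25.7% of those higher in tbGFP-positive cells at these times. Genes with counts only in tbGFP-positive cells can pass the filter on counts. The tested receptor genes and pseudogenes may therefore be weighted towards higher calls, which was not tested.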
